A study of Caenorhabditis elegans with 6 samples.

How the data were processed

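The series measured DamID in whole Caenorhabditis elegans animals at the L4 larval stage. In DamID a protein is expressed as a fusion with the bacterial DNA adenine methyltransferase Dam, which methylates adenine in GATC sequences near the places the protein occupies, and the methylated sites are cut out with DpnI, amplified by PCR and sequenced. The labels describe 3 constructs, namely Dam fused to lmn-1 (the nuclear lamin), to mel-28 (a component of nuclear pores) and to gfp (a protein with no binding site of its own on chromatin), each driven by the uninduced hsp-16.41 heat-shock promoter. Each construct was sampled in hermaphrodites and in males, which gives 6 samples. The labels state 20 animals per sample and 10 worms per tube, grown at 25 °C on an E. coli lawn, and say that the reads include contaminating E. coli.

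Per the submitters' processing notes, cutadapt, Bowtie and SAMtools were used with the genome build ce10. The versions, the order and the parameters of these tools are not given in the sources used here. The authors deposited a linear ratio for each 100 kb bin, relative to the strain coded PMW124, for the strains coded PMW123, PMW124 and PMW179 in each sex. The labels do not say how libraries were combined and scaled to give a ratio. On inspection of the deposited count table, the ratios matched the mean, over same-numbered columns, of the strain's share of reads in a bin divided by the share of PMW124, with shares taken over all counts including the mitochondrial bin. By this match, a ratio would be an average of library pairs. This match was seen before the count table was set aside and was not recomputed. Per the file headers the strains carry these codes, and no label ties a code to a construct. The strains are therefore named by code throughout, and it is not stated which code is the lamin, the pore or the gfp fusion. A second deposited table holds whole-number read counts, and its 12 columns are named by the same strain codes, a sex and a number. These columns give 2 per strain code and sex. They match the strain codes and sexes of the ratio table, but could not be matched to a labelled sample or construct. Counts per library were to be used only with such a match, and for that reason were not used. The ratio columns lack that match too and were used by code, as the authors' own comparisons. Tests by strain code on the counts were thus left out by choice.

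The design fixed before the data were examined had been written for counts, with quasi-likelihood count models across all libraries. None of those models was fitted, because the count columns were not used. The comparisons that need no counts were made on the deposited ratios: the level of X against the autosomes, its difference between the sexes, chromosome arms against centres, the parts of X, and correlations across bins. The ratio table has 1 value per bin, strain and sex. A replicate check by strain code would need the count columns and was not made, so no p-value is given. The number of reads behind a ratio is likewise not in the table used, so no counting interval or detection limit is given.

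Ratios were converted to log2 without a pseudocount. Bins listed as NA, Inf or 0 were left out of the main values. Among 1005 nuclear bins this left 992 for PMW123 in hermaphrodites, 996 for PMW123 in males, 992 for PMW179 in hermaphrodites and 996 for PMW179 in males. Of the 178 bins of X, 171 were left for PMW123 and 173 for PMW179 in males, against 176 for each in hermaphrodites. Chromosomes III and V kept fewer bins in hermaphrodites than in males. The single mitochondrial bin entered no comparison. The files number the bins and give no coordinates, so positions were taken as consecutive 100 kb steps from the start of each chromosome in ce10, 1-based. The number of bins per chromosome equalled the number that the last gene of the WBcel235 gene table reaches for 6 of 6 chromosomes. That gene table belongs to another build, so no gene was placed in a bin and the fixed gene lists were not run.

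The level of a chromosome was the median log2 ratio of its bins. X enrichment was the X median minus the median of all autosomal bins, and each autosome was set against the other autosomes in the same way. The sex difference was the log2 ratio in males minus that in hermaphrodites, bin by bin. The median of X was also placed among 10000 random lists of autosomal bins of the same number. The lists were drawn without matching on read depth, because no counts were used, and did not keep neighbouring bins together. The X median was also placed among autosomal windows of 50 consecutive bins. These windows moved bin by bin, so they overlap and are not independent comparisons, and each holds fewer bins than X. Each chromosome was split into 3 parts of equal bin number. Arm minus centre was the median of the bins in the outer parts minus the median of those in the middle part, averaged over the 5 autosomes. Pearson and Spearman correlations were computed across bins, which are not independent replicates. The median absolute step between neighbouring bins served as a measure of how far single bins scatter. The named bins are, by the rule fixed beforehand, the 3 highest and the 3 lowest in each strain and sex and in each sex difference. The rule's minimum of read counts was not applied, and its parts on bins past a test and on domains of such bins did not apply.

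The calculations were tested on 100 simulated tables of 1005 nuclear bins with known X enrichment and known arm minus centre. The mean estimate differed from the truth by at most 0.021 on the log2 scale, and the SD of an estimate over simulations was at most 0.154. Simulated bins were independent of their neighbours, unlike real ones. Alternatives covered the use of means in place of medians, other reference bins, a split into 4 parts in place of 3, chromosome ends, left-out autosomes and bins listed as 0 or Inf. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.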

Results

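DamID ratios were available for 1005 bins of 100 kb on the 5 autosomes and X of C. elegans, for the strains coded PMW123 and PMW179 relative to the strain coded PMW124, in hermaphrodites and in males. Hermaphrodites carry 2 X chromosomes and males 1, and a ratio within a sex compares strains that carry the same number. In the authors' deposited table PMW124 had the ratio 1 in each of the 992 bins with a value in hermaphrodites and in each of the 998 bins in males, so it was the denominator. Leaving out bins listed as Inf or 0, the ratios of PMW123 ranged from 0.0933 to 10.6 in hermaphrodites and from 0.0191 to 8.22 in males. With the same exclusion, those of PMW179 ranged from 0.333 to 7.21 in hermaphrodites and from 0.104 to 7.42 in males. The ratio table gives 1 value per bin, strain and sex, with no depth and no replicate values. The deposited count table holds numbered columns for each strain code and sex, and was not used here. Neighbouring autosomal bins differed by a median of 0.66 and 0.61 (log2) for PMW123 in hermaphrodites and males, and by 0.51 and 0.53 for PMW179. On X these steps were 0.54 and 0.85 for PMW123, and 0.45 and 0.60 for PMW179. Bins on X thus scattered more than autosomal ones in males, and less in hermaphrodites. Single bins are therefore reported as values, and the comparisons rest on many bins.

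The first comparison asked which chromosomes each strain marked more or less than the denominator strain, a question tied to the position of X in the nucleus in the 2 sexes. For PMW123, X had the lowest median in both sexes and V the highest, though in hermaphrodites III lay close to X. In medians over bins of the authors' deposited table, X had a ratio of 0.803 in hermaphrodites and 0.709 in males, whereas V had 1.36 and 1.43. Chromosome IV followed V, with 1.15 and 1.19, and chromosome III lay lowest among the autosomes, with 0.818 and 0.854. Relative to all autosomal bins, X had a log2 level of -0.38 in hermaphrodites (0.767-fold) and -0.62 in males (0.649-fold). Only 52 of 176 X bins in hermaphrodites and 49 of 171 in males lay above the autosomal median.

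The X level of PMW123 was below the median of each of 10000 random lists of autosomal bins in both sexes. These lists draw scattered bins, and whole autosomes also fell outside them. The median of V, 0.45 (log2) in hermaphrodites and 0.52 in males, was above the highest list, at 0.35 and 0.44. That of III in hermaphrodites, -0.29, was below the lowest list, at -0.24, though not in males. X was not below all autosomal regions: among 582 overlapping autosomal windows of 50 consecutive bins, 222 were lower in hermaphrodites and 197 in males. Single autosomes also stood apart from the others by similar amounts, from -0.39 for III to 0.52 for V in hermaphrodites and from -0.40 to 0.51 in males. Without chromosome V in the reference, the X enrichment in hermaphrodites was -0.24.

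For PMW179 the autosomes lay close together and X depended on the sex. In males the median X ratio in the authors' deposited table was 1.68, against 0.980 over all autosomal bins, so X was 1.71-fold higher than the autosomes (log2 0.78). This was seen along most of the chromosome, with 152 of 173 X bins above the autosomal median. No autosome departed from the others by more than 0.13 (log2) in these animals. In hermaphrodites the median X ratio was 1.09 and the autosomal one 1.20, so X was slightly lower than the autosomes (log2 -0.14, 0.909-fold), with 60 of 176 bins above the autosomal median. The 5 autosomes spread there from -0.09 to 0.07 against one another.

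The male X of PMW179 was above the median of each of 10000 random lists of autosomal bins. It was also above all 582 overlapping autosomal windows, the highest of which had a log2 ratio of 0.19. The lowest of 129 windows on X had 0.40. In hermaphrodites 3 of the 10000 lists and 19 of the 582 windows lay below X.

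**Figure D1:**
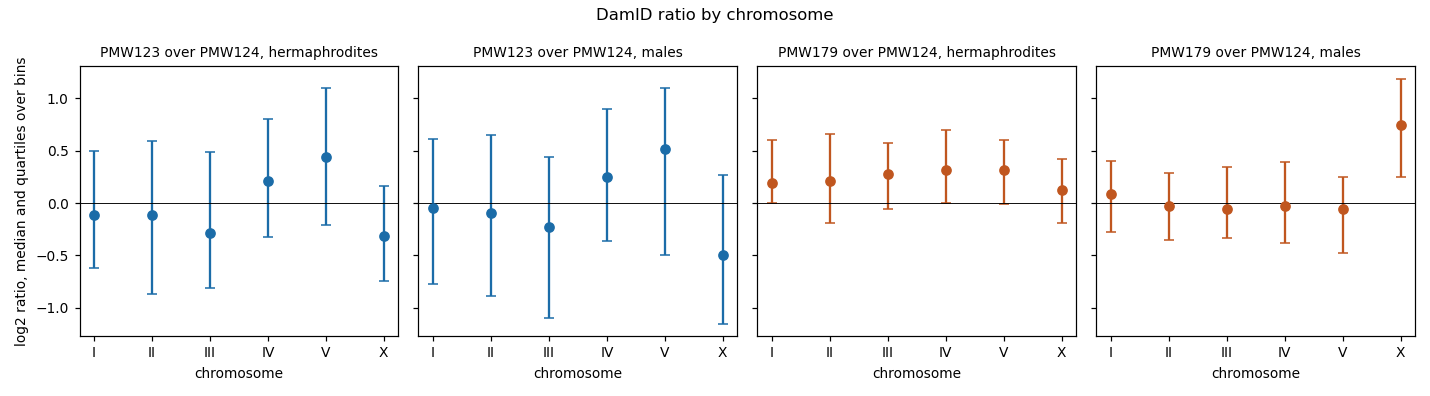
Median log2 DamID ratio of the bins of each chromosome (points) with the quartiles over bins (bars), for PMW123 and PMW179 over PMW124 in each sex. X is the lowest chromosome for PMW123 in both sexes, in hermaphrodites at -0.32 with III close to it at -0.29. For PMW179 in males X is the highest, at 0.75 against 0.08 or less on the autosomes.

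The second comparison set males against hermaphrodites within each strain. In the authors' deposited table the ratio of PMW179 on X was higher in males, by a median of 0.58 (log2) over 171 bins, while it was lower on each autosome, from -0.14 on I to -0.40 on V. If ratios come from shares of all reads, as the match on inspection implies, a larger share elsewhere could lower every autosome. Whether it did so here was not tested. In hermaphrodites the median ratio of PMW179 was above 1 on every chromosome, from 1.09 on X to 1.25 on IV. The levels of the sexes are therefore relative and do not show that PMW179 marked the autosomes less in males. Relative to the autosomal median difference of -0.29, X was higher in males by 0.87, a 1.82-fold difference, and 150 of 171 X bins lay above that median. All 10000 random lists and all 582 overlapping autosomal windows were below X. The largest departure of an autosome from the others was 0.20. With X split into 3 equal parts, the difference relative to the autosomes was 0.86 in the left part, 0.70 in the middle part and 1.11 in the right part.

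For PMW123 the sex difference of X was smaller and of the other sign. Its median difference on X was -0.16 and on the autosomes -0.03, which gives -0.13 for X relative to the autosomes. The autosomes ranged from -0.10 to 0.20 against one another, and 206 of 582 autosomal windows had a lower difference than X. Among random lists of autosomal bins, 285 of 10000 had a median below that of X and 9715 had one above it. The parts of X differed: the left part had -0.16, the middle part -0.49 and the right part 0.15 relative to the autosomes. The 2 strains share the PMW124 denominator of each sex. Set directly against each other, PMW123 over PMW179 had a log2 level on X relative to the autosomes of -0.22 in hermaphrodites and -1.29 in males. That direct comparison may remove the denominator only in part, because on inspection the ratios matched averages of library pairs. Neither the sex differences nor their difference between strains was tested here, since the count columns were not used.

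**Figure D2:**
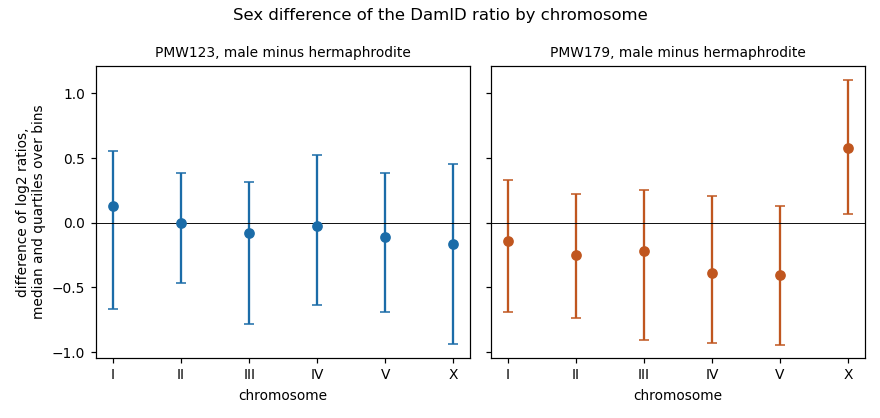
Difference of the log2 DamID ratio between males and hermaphrodites on each chromosome, as the median over bins (points) with the quartiles (bars), for PMW123 and PMW179. For PMW179, X lies at 0.58 and the autosomes between -0.40 and -0.14; for PMW123, X lies at -0.16 within the quartiles of every autosome.

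The next comparison followed the ratios along the chromosomes, each split into 3 equal parts, of which the outer ones stand for the arms and the middle one for the centre. C. elegans autosomes have gene-dense centres flanked by arms that are richer in repeats. PMW123 had higher ratios on arms than in centres on 5 of 5 autosomes in both sexes. In the authors' deposited table the arms exceeded the centre by a mean of 0.93 (log2) in hermaphrodites, a 1.91-fold difference, with values from 0.67 on IV to 1.17 on II. In males the mean was 1.28, or 2.43-fold, with values from 0.74 on IV to 1.56 on II. Among the parts of autosomes, the centre of II had the lowest median in both sexes, with -0.93 in hermaphrodites and -1.19 in males. The right arm of V had the highest, with 0.94 and 0.92.

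X had a weaker contrast between arms and centre for PMW123, with 0.15 in hermaphrodites and 0.70 in males. In males the middle part of X was at -1.12 relative to the autosomal median (0.459-fold, with 8 of 57 bins above it), against -0.42 for the left part and -0.44 for the right part. In hermaphrodites the left part of X was nearest to the autosomes, with -0.26, followed by -0.52 in the middle part and -0.54 in the right part. The values at the left end depended on where the arm was cut. With each arm taken as 1 of 4 equal parts, the left part of X was at -0.13 in hermaphrodites and -0.072 in males, and the contrast on X in hermaphrodites was 0.34.

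PMW179 had smaller contrasts between arms and centres on the autosomes and on the male X. On X in hermaphrodites its contrast was -0.21, larger in size than the 0.15 of PMW123. In hermaphrodites the PMW179 ratios were lower on arms than in centres on 5 of 5 autosomes, by small amounts with a mean of -0.21 and a range from -0.35 on II to -0.05 on I. In males the mean was 0.08, with 3 autosomes above 0 and 2 below. The male X of PMW179 was nearly level, at 0.68, 0.78 and 0.85 above the autosomal median in the left, middle and right part, and its arm minus centre was 0.0088.

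**Figure D3:**
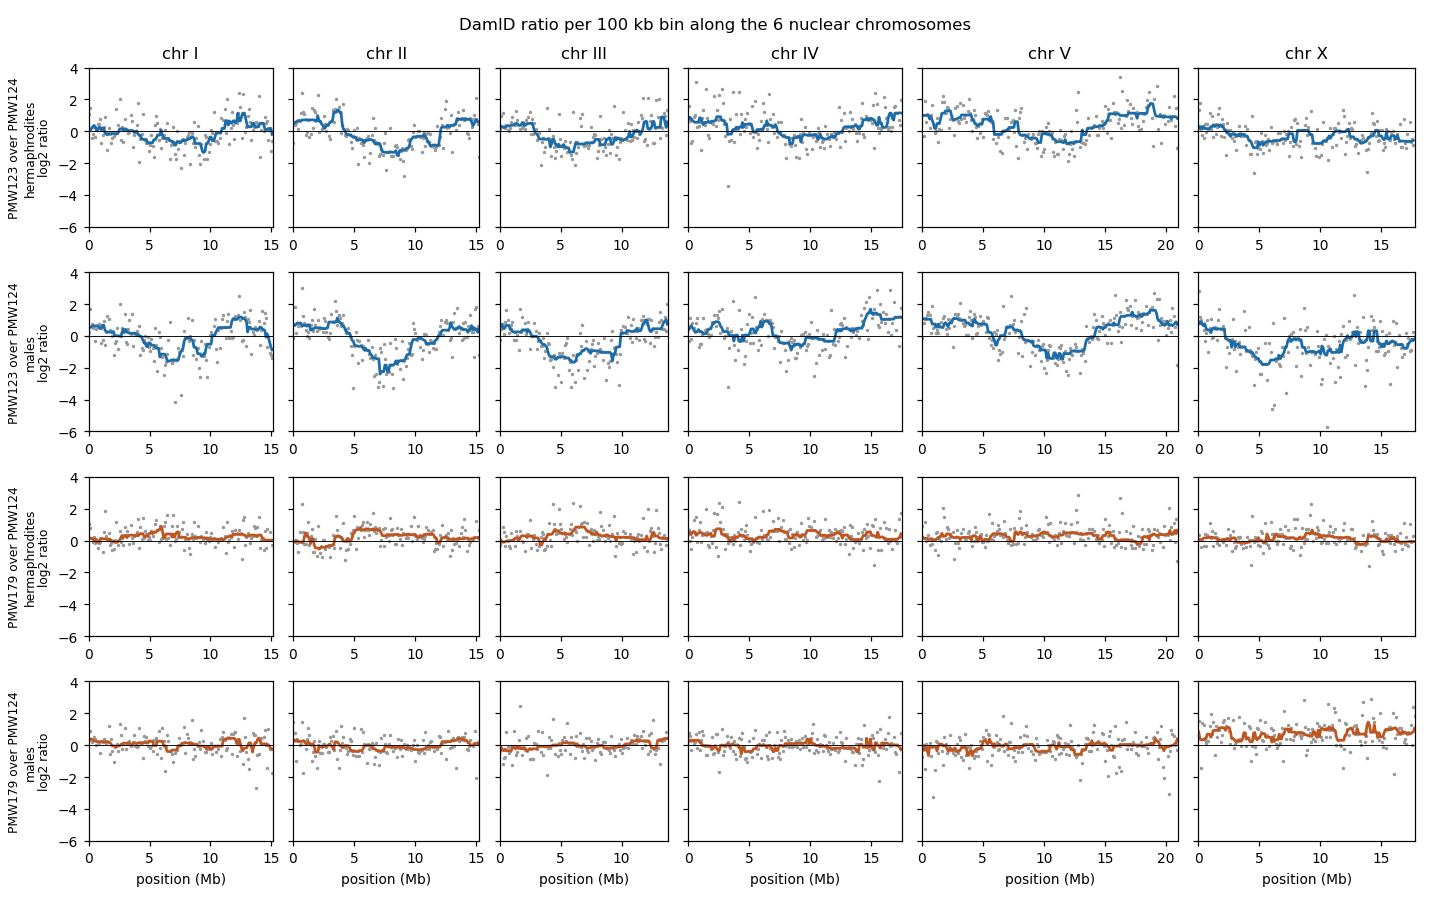
Log2 DamID ratio of each 100 kb bin (points) along the chromosomes, in Mb of ce10, with the running median over 11 bins (lines), for PMW123 and PMW179 over PMW124 in each sex. PMW123 dips in the autosomal centres, and PMW179 in males is level on the autosomes and higher on X.

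**Figure D4:**
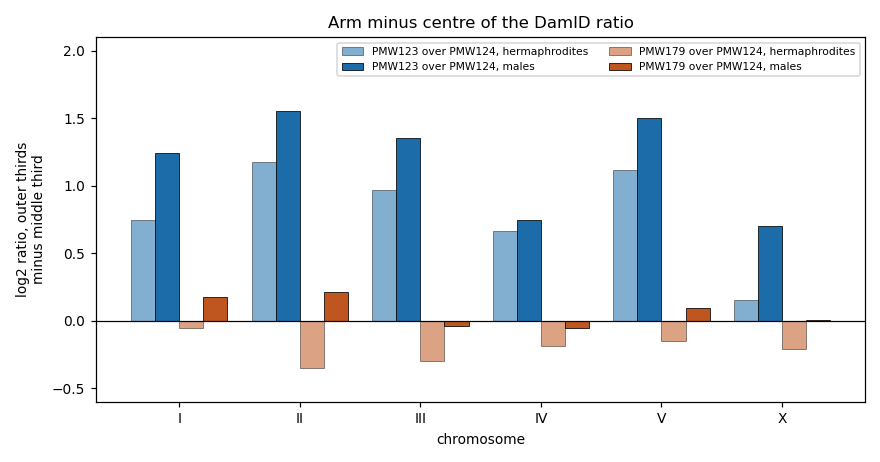
Median log2 DamID ratio of the outer parts of each chromosome minus that of its middle part, with each chromosome split into 3 equal parts, for PMW123 and PMW179 over PMW124 in each sex (bars, from 0). PMW123 is above 0 on each chromosome, with autosomal means of 0.93 in hermaphrodites and 1.28 in males.

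The fourth comparison asked how alike the profiles were. Across bins of the authors' deposited table the PMW123 profiles of the sexes were similar, with Pearson r = 0.64 and Spearman rho = 0.65 over 985 bins. The PMW179 profiles of the sexes showed no such likeness, with r = -0.0070 and rho = -0.0039 over 986 bins, and r = 0.03 on the autosomes alone. Their SD over autosomal bins was 0.60 in hermaphrodites and 0.62 in males, with median steps between neighbours of 0.51 and 0.53. For PMW123 the SD was 0.99 and 1.12, with steps of 0.66 and 0.61. Scatter of single bins could therefore hide a likeness of the PMW179 profiles. Between strains, r was 0.39 (rho 0.31) in hermaphrodites and 0.10 (rho 0.12) in males, and within a sex both ratios have the same denominator, which alone gives a correlation above 0. Between strains of different sex, which share no denominator, r was -0.10 for PMW123 in hermaphrodites with PMW179 in males and -0.04 for PMW123 in males with PMW179 in hermaphrodites. The covariances were 0.22 and 0.09 within hermaphrodites and males, against -0.07 and -0.03 across sexes. No chance value for the shared denominator was simulated, since that needs read counts, so part or all of the correlation within a sex may come from it.

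Single bins at the ends of the rankings followed these chromosomal patterns in part. Bins listed as Inf or 0, among them 2 listed as 0 in males for each strain, were left out of the rankings. In males, bins on X also scattered more than autosomal ones, so their place at an end may partly reflect scatter. In the authors' deposited table the highest PMW123 ratios in hermaphrodites were 10.6 at V 16200001 to 16300000, 8.44 at IV 600001 to 700000 and 7.22 at V 19200001 to 19300000, and in males these bins had 2.81, 1.73 and 4.90. The highest in males were 8.22 at II 700001 to 800000, 7.47 at IV 15400001 to 15500000 and 7.39 at IV 16500001 to 16600000. All 6 lie on an autosomal arm as defined above, but these arms hold most autosomal bins, so this says little. The lowest in hermaphrodites in the authors' deposited table were 0.0933 at IV 3200001 to 3300000, 0.143 at II 9100001 to 9200000 and 0.161 at X 4500001 to 4600000. Of these, the bin on II lies in the middle part of its chromosome, and those on IV and X lie in an outer part. The lowest in males lay on X, with 0.0191 at 10500001 to 10600000, 0.0421 at 6000001 to 6100000 and 0.0485 at 6200001 to 6300000. These 3 X bins also had the lowest sex difference of PMW123, since their ratios in hermaphrodites were 0.733, 0.598 and 0.669. The bins with the highest sex difference of PMW123 were IV 15200001 to 15300000 (6.47-fold higher in males), I 6600001 to 6700000 (6.14-fold) and I 4100001 to 4200000 (5.98-fold).

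For PMW179 the highest male ratios in the authors' deposited table were all on X, with 7.42 at 14100001 to 14200000, 7.27 at 8600001 to 8700000 and 6.45 at 13500001 to 13600000. Their ratios in hermaphrodites were 1.22, 0.886 and 1.25. The highest sex differences were also on X, namely at 8600001 to 8700000, at 14000001 to 14100000 (0.333 in hermaphrodites and 2.41 in males) and at 10600001 to 10700000 (0.912 and 5.96). The highest ratios in hermaphrodites lay on autosomes, with 7.21 at V 12800001 to 12900000, 6.30 at V 16200001 to 16300000 and 5.24 at IV 4100001 to 4200000. In the authors' deposited table the lowest in hermaphrodites were 0.333 at X 14000001 to 14100000, 0.339 at IV 15200001 to 15300000 and 0.352 at X 4300001 to 4400000. The lowest above 0 in males were 0.104 at V 900001 to 1000000, 0.121 at V 20200001 to 20300000 and 0.156 at I 13700001 to 13800000. The first of these bins is listed as Inf in hermaphrodites. Among bins with a finite ratio above 0 in both sexes, which leaves out V 900001 to 1000000, these had the lowest sex differences: V 20200001 to 20300000 (4.16 in hermaphrodites and 0.121 in males), IV 2500001 to 2600000 (5.10 and 0.311) and V 1700001 to 1800000 (4.13 and 0.418). The bin at V 16200001 to 16300000 ranked among the highest in hermaphrodites for both strains, which share that denominator.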

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

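The tests of explanations in this part were chosen after the values had been seen, except the direct comparison of the strains for arms and centres. The X level of PMW179 relative to the autosomes had opposite signs in the sexes, 0.78 (log2) in males and -0.14 in hermaphrodites. The sex difference of X also had opposite signs in the strains, 0.87 for PMW179 and -0.13 for PMW123. The PMW123 value is small, and its sign is uncertain. For that strain single autosomes departed from the others by -0.10 to 0.20, and the parts of X ran from -0.49 to 0.15. Neither the contrast between sexes nor that between strains was tested here. The ratio table gives 1 value per strain and sex, and the numbered count columns were not used.

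A lower level of X in the male PMW124 libraries would raise both strains alike, yet the X shift of PMW123 was -0.13 relative to the autosomes and at most 0.15 in its highest part of X, against 0.43 for 50% of the PMW179 shift, so it is argued against as the sole cause unless PMW123 moved the other way. Hermaphrodites among the animals of the PMW179 male samples stay open: their second X could raise the ratio by up to 1 (log2), against a male excess of 0.78 and a sex difference of 0.87, which would need 71.4% and 82.5% hermaphrodites. The sex difference was 0.86, 0.70 and 1.11 in the left, middle and right part of X, so the right part passes that limit, though by less than the parts differ. The autosomal profiles of the PMW179 sexes hardly correlated (r = 0.03), against r = 0.67 for PMW123 with the same denominators. This does not decide on such a mixture, because the PMW179 profile is weaker and scatter of single bins could hide a likeness. A sex difference in what PMW179 marks also stays open and untested.

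Arms and centres of the autosomes had opposite signs in the strains in hermaphrodites, with arm minus centre above 0 on 5 of 5 autosomes for PMW123 and a mean of -0.21 for PMW179, below 0 on 5 of 5. This was not tested. In males the PMW179 mean was 0.08. For PMW123 over PMW179 directly, arm minus centre was 1.22 in hermaphrodites and 1.21 in males. The strains thus differed in both sexes, but the sign for PMW179 alone also depends on the PMW124 denominator. Arm minus centre was larger in males than in hermaphrodites by 0.36 for PMW123 and by 0.35 for PMW179, as means over autosomes of the bin by bin differences, with 4 of 5 autosomes above 0 for PMW123 (IV at -0.036) and 5 of 5 for PMW179. For PMW123 over PMW179 directly, the same sex difference was 0.017. A candidate explanation for the larger male contrast of PMW123 is therefore a sex difference in the PMW124 denominator, with centres higher relative to arms in males than in hermaphrodites. A parallel change of PMW123 and PMW179 would give the same values. If the ratios average library pairs, as the match on inspection implies, the direct comparison removes the denominator only in part.

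The mitochondrial bin, which entered no comparison, had ratios above the denominator's 1 in the authors' deposited table: 1.84 for PMW123 in hermaphrodites, 2.04 for PMW123 in males, 4.52 for PMW179 in hermaphrodites and 5.82 for PMW179 in males.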

How the results depend on the processing

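Of 148 alternative values for 33 results, 134 lay within 0.1 (log2 units, or units of r) of the reported value, a margin chosen after the data were seen, and 14 moved further. None of the 14 changed sign, and 4 values no larger than 0.1 did: the X arm minus centre of PMW179 in males under 2 settings, the middle of X for PMW179 in hermaphrodites, and the correlation of the PMW179 sexes. The cause of the shifts was not tested. Without chromosome V in the reference, the X enrichment of PMW123 was -0.24 in hermaphrodites and -0.50 in males. With all nuclear bins as the reference it was -0.49 in males, and the sex difference of X for PMW179 was 0.70. With chromosomes split into 4 parts, arm minus centre of PMW123 was 0.34 on X in hermaphrodites and 1.18 on the autosomes in males. The same split put PMW123 in hermaphrodites at -0.13 in the left and -0.62 in the middle part of X, PMW123 in males at -0.072 in the left and -0.54 in the right part, and PMW179 in hermaphrodites at -0.32 in the right part. Without chromosome IV, the autosomal arm minus centre of PMW123 in males was 1.41. With means in place of medians, the right part of X for PMW123 in males was at -0.33. On autosomal bins alone, the sex differences of the strains correlated with r = 0.59, against 0.47 on all nuclear bins. Both differences contain the same PMW124 denominators, which alone give a correlation above 0. How much they give was not simulated, so these values cannot show whether the strains are alike. Only the split into 4 parts and the restriction to autosomal bins had been planned. Settings listed before the data were examined that need counts were not run: TMM and DESeq2 scaling, count filters, pseudocounts, summed counts, left-out libraries and left-out bins of highest count. The X-to-autosome read ratio and the tests of single bins were not run either. No paired analysis was run, because the numbered count columns were not used. The depth, not given in the ratio table, limits every single bin.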

Other observations

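The tests and windows in this part were chosen after the values had been seen. Along X split into 10 equal parts, the leftmost was the only part where PMW123 lay above the autosomal median, with 0.23 (log2) in hermaphrodites and 0.37 in males. The fourth part had the lowest male value, -1.56, against -0.66 in hermaphrodites. PMW179 in males lay between 0.37, also in the fourth part, and 0.97 in the seventh. Among windows of 10 bins with at least 8 values, the highest PMW123 median was on the right arm of V in both sexes, 3.49-fold at 18400001 to 19400000 in hermaphrodites and 3.23-fold at 18700001 to 19700000 in males. The lowest was in the centre of II in both sexes, 0.376-fold at 7300001 to 8300000 in hermaphrodites and 0.200-fold at 6800001 to 7800000 in males, where 10 of 10 bins were below 1. For PMW179 the highest window was at III 6400001 to 7400000 in hermaphrodites (1.93-fold) and at X 13500001 to 14500000 in males (2.55-fold).

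In hermaphrodites PMW123 and PMW179 correlated across autosomal bins (r = 0.36) although their arms and centres had opposite signs. Noise in the shared PMW124 denominator could give this. Across sexes, where no denominator is shared, the higher of the correlations was -0.055. This test does not decide, since PMW179 hardly correlates with itself across sexes (r = 0.03), so a real likeness in hermaphrodites stays open.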
